A study of Homo sapiens with 6 samples.

How the data were processed

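RNA sequencing libraries from HEC-1-A, an established human endometrial adenocarcinoma cell line, were compared between cells carrying an RNA interference construct against NCAPG and control cells, with 3 libraries in each group. The sample titles name an RNA interference control, and the series' design text calls the control an empty vector. Groups and replicate numbers were read from the sample titles, and each column of the table was matched to its sample by the sample's description. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit. A strand-marking step, the interference sequences, the time after transfer of the construct and whether the 3 libraries of a group came from separate cultures were not given in the sources used here. The p-values therefore measure the spread between these libraries, which may be technical in part.

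The deposited table holds raw read counts per gene symbol, 1 column per library, not normalized and not pooled. STAR, HTSeq 0.6.0, DESeq2 and the genome build hg38 are named in the submitters' processing notes. Annotation release, strand setting and filters were not given in the sources used here. All 19932 symbols of the table occur in GENCODE release 29 (GRCh38, the same assembly as hg38), and 19907 of them are protein coding there, so library totals cover reads assigned to protein-coding genes almost alone. The table has no row for unassigned reads, and no column of another series. Coordinates, gene types, transcript sequences and 3' UTRs were taken from GENCODE release 29. GC content and transcript length were available for each symbol, and a 3' UTR of at least 50 bases for 19167 of them. Library totals were 13106829, 14349970 and 15830175 counts for control replicates 1 to 3 and 13995811, 13487731 and 13300202 for knockdown replicates 1 to 3. In data simulated from these means, library sizes and dispersions, 86.0% of genes changed 1.5-fold, 88.0% of those changed 2-fold and 57.1% of those with the smallest simulated change, which was under 1.5-fold, were recovered among 12290 genes tested, and 7.3% of the calls were unchanged genes. Few genes were changed in the simulation, which gave 178 calls against 2756 in the real comparison. An adjusted p below 0.05 therefore demanded a smaller unadjusted p in the simulation, and its shares do not carry over directly.

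Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (12387 of 19932), libraries were scaled by TMM, and a quasi-likelihood F-test (glmQLFit with robust estimation, glmQLFTest, two-sided) compared the groups with all 6 libraries and no further covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was derived from the F statistic. CPM, the usual depth-scaled counts, use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. All log2 fold changes are knockdown minus control.

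The 31 gene lists were written from textbook knowledge, and none was chosen by the study on these samples. Each was compared with the other genes by camera (limma 3.58.1, preset inter-gene correlation of 0.01, two-sided), with Benjamini-Hochberg adjustment over the 31 lists. Camera was repeated with the correlation estimated from the data. Fry was run on the same 31 lists and adjusted over them. It is given for the main list, as a range for the lists called by camera, and for some others. Counts of changed members are given over all genes tested and, where stated, adjusted over the list alone. The genes named were fixed by a rule: NCAPG; PIK3CA, AKT1 and MTOR; MKI67, CDH1 and VIM; the 8 genes with the largest positive and the 8 with the largest negative log2 fold change among called protein-coding genes with at least 5 CPM in the higher group and no overlap between the groups; and per list the up to 3 called members with the smallest p-value, or the most abundant member where none was called. Some genes that the rule selects are not reported here. Other list members are named as examples chosen after their values were seen; for the lists they come from, calls under every alternative were computed for all called members.

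The lists, the rule, the tests and the following alternatives were fixed before the data were examined: DESeq2 1.42.0, RLE scaling, scaling by library size only, no count filter, a filter of at least 1 CPM in at least 3 libraries, limma-voom, the replicate number as a block, an adjusted p threshold of 0.01, and leaving out each library in turn. Removal of GC and length trends and removal of the 20 most abundant genes were added after the data had been seen. The replicate numbers were not treated as pairs in the main test, a choice fixed beforehand. Deviations from the group means of same-numbered libraries correlated at -0.107, 0.029 and -0.0263. No pair of libraries agreed within sampling noise: the chi-square statistic per degree of freedom was between 2.452 and 9.371 within groups. No library is therefore a copy of another, and each was treated as 1 sample. This does not show that they came from separate cultures. For each named gene, the share of its 50-mers found in transcripts of other genes and exon overlap with other genes of the table were computed, since reads in such parts can be lost or misassigned. Python 3.11.15 with scipy 1.17.1 was used for the sequence searches.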

Results

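The transcriptome of HEC-1-A endometrial adenocarcinoma cells was profiled by RNA sequencing after RNA interference against NCAPG, a non-SMC subunit of condensin I, the complex that compacts chromosomes in mitosis. Control cells formed the comparison group, titled an RNA interference control in the sample names and an empty vector in the series' design text, and each group had 3 libraries. Library totals ranged from 13106829 to 15830175 counts over 19932 genes, of which 14971 to 15095 had at least 1 count in a given library. The first principal component of log2 CPM held 52.15% of the variance and separated the groups, with control libraries between -19.25 and -17.69 and knockdown libraries between 17.86 and 18.87. Libraries of a group were close to each other, with Pearson correlations of log2 CPM between 0.99113 and 0.99395 within groups and between 0.98439 and 0.98638 across them.

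NCAPG itself was the first gene examined, because its level checks the labels. NCAPG (ENSG00000109805.9, GRCh38 chromosome 4, 17810902 to 17844862, plus strand, protein coding) fell from 112 ± 4.54 CPM in control cells to 44.7 ± 2.92 CPM in knockdown cells (SD, n = 3 each). This is a 2.52-fold decrease, a log2 fold change of -1.33 ± 0.068 (SE), with an adjusted p of 1.06e-10 by edgeR. The lowest control library held 107.7 CPM and the highest knockdown library 47.7 CPM. Exons of NCAPG overlap those of LCORL on the opposite strand, and 33.33% of its 50-mers also occur in LCORL transcripts, so reads from that part cannot be told apart without a known strand setting. The same kind of limit holds, to differing extents, for PIK3CA, TGM2, NCAPD2, STAG2, FOXM1, MCM2, FANCI, FANCD2, PLK3, JUNB, BNIP3L, KRT18, IFIT2 and SOD2, each of which overlaps exons of a gene on the other strand. The share of 50-mers found in that gene was 37.09% for PIK3CA but 1.19% for PLK3 and 0.47% for IFIT2. For STAG2 and BNIP3L, 0.0% and 0.2% occur in any other gene. LCORL rose from 18.3 ± 0.37 to 23.0 ± 0.99 CPM (log2 fold change 0.33 ± 0.090, adjusted p = 0.0139). Of the other 7 condensin subunits on the list 0 passed the threshold in the edgeR test, also adjusted over the list alone, and 1 had an unadjusted p below 0.05 (0 called by DESeq2 and 0 by limma-voom, camera adjusted p = 0.945). Their log2 fold changes lay between -0.11 for NCAPD2, at 393 ± 16.8 CPM in control cells, and 0.13 for SMC2.

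The comparison of knockdown with control cells asked which transcripts differ when NCAPG is lowered. Of 12387 genes tested, 1318 were higher and 1438 were lower in knockdown cells. Most changes were small: the median absolute log2 fold change of called genes was 0.33, and 130 genes rose and 91 fell by at least 2-fold. In 2674 of the 2756 called genes every library of one group lay above every library of the other, as in 37.01% of all genes tested, where chance gives 10%. Large increases included RAB25, a small GTPase of apical vesicle recycling, which rose 8.66-fold from 1.84 ± 0.56 to 16.1 ± 1.16 CPM (chromosome 1, 156061160 to 156070514), and CALB1, the calcium-binding protein calbindin, which rose 5.36-fold from 26.1 ± 1.98 to 140 ± 2.55 CPM (chromosome 8, 90058608 to 90095475). CDH16, a cadherin of kidney epithelium, rose 3.83-fold to 66.9 ± 6.35 CPM. PROM2, SLC44A5, FGB and SLC5A9 rose by log2 fold changes of 2.19 ± 0.25, 2.05 ± 0.19, 2.03 ± 0.21 and 1.82 ± 0.17, all from control levels under 4 CPM. UGT1A6 rose by 2.11 ± 0.22, but 73.79% of its 50-mers also occur in other genes and its exons overlap those of other UGT1A genes on the same strand, so its counts are uncertain.

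Among the large decreases, TGM2, a protein cross-linking transglutaminase whose exons overlap those of RPRD1B on the opposite strand, fell 3.89-fold from 204 ± 6.07 to 52.4 ± 1.08 CPM (chromosome 20, 38127387 to 38166578), and CDK6, a G1 cyclin-dependent kinase, fell 3.81-fold from 67.5 ± 6.95 to 17.7 ± 2.08 CPM (chromosome 7, 92604921 to 92836594). KRT81, a hair keratin, fell by a log2 fold change of -2.49 ± 0.12, with 38.35% of its 50-mers shared with KRT86, so its counts are uncertain. ANKRD1 and CDH4 fell by -1.83 ± 0.19 and -1.93 ± 0.24, EDN2 (endothelin 2) by -1.55 ± 0.18 and SERPINB5 (maspin) by -1.54 ± 0.16. Without knockdown replicate 2 the count of lower genes was 867, without control replicate 3 it was 920, and without knockdown replicate 3 it was 946. With scaling by library size only, 1689 genes were higher and 1050 lower. The 3' UTRs of PROM2, SLC44A5, SLC5A9 and CDK6 hold the 7-mer GTGTCAC, and the 1281 genes with it had a mean log2 fold change, adjusted for 3' UTR length and GC content, of 0.047 ± 0.0099 (SE), against -0.0055 ± 0.0033 in the 11004 genes without it.

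**Figure D1:**
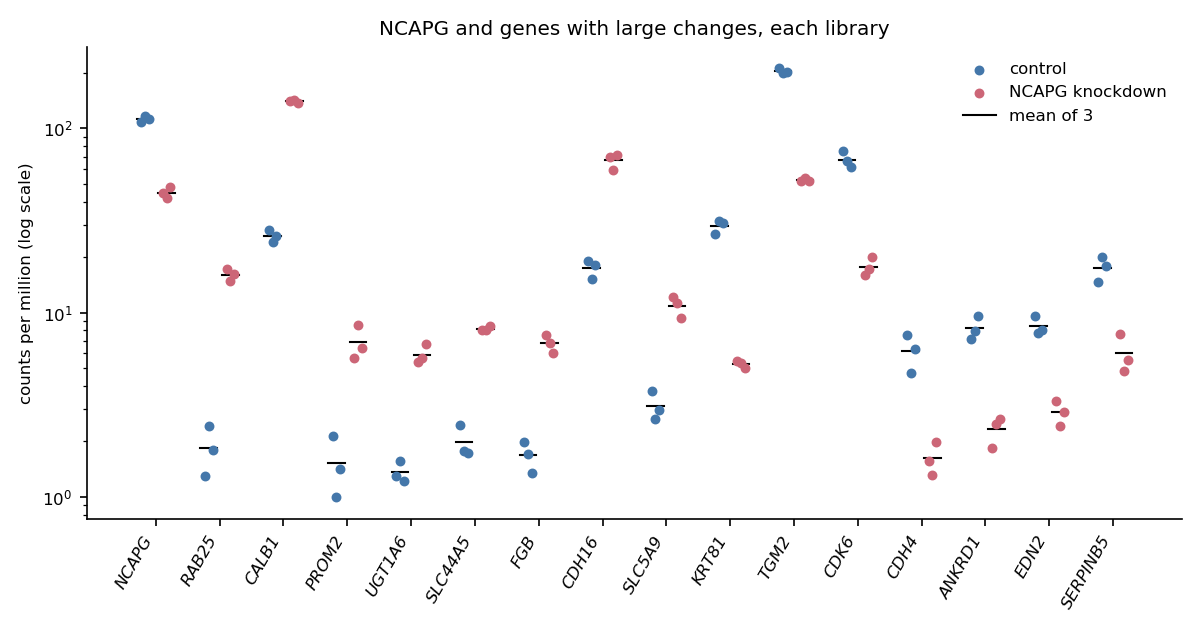
CPM (log axis) of NCAPG, the 8 genes with the largest increase and 7 of the 8 with the largest decrease under the naming rule. The rule takes called protein-coding genes with at least 5 CPM in the higher group and no overlap between the groups. Points are the 3 control (blue) and 3 knockdown (red) libraries, with the mean of 3 as a black line. The groups do not overlap in any of these genes, which the rule requires of all but NCAPG, and NCAPG moves from 112 to 44.7 CPM.

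The series title names PI3K/AKT/mTOR signalling, so the component genes of this pathway formed the main list. Its members moved in both directions. Of 34 members tested, 5 rose, 7 fell and 22 did not pass the threshold, and adjusted over the list alone 9 rose and 9 fell. INSR, the insulin receptor, rose from 7.87 ± 1.01 to 15.6 ± 1.54 CPM (log2 fold change 0.99 ± 0.13, adjusted p = 1.84e-05). AKT1 (chromosome 14, 104769349 to 104795751) rose from 208 ± 11.9 to 253 ± 8.09 CPM (0.29 ± 0.056, adjusted p = 0.00112), and RICTOR, a subunit of mTOR complex 2, rose by 0.36. GAB1 and DEPTOR rose by 0.45 and 0.58. INPP4B, a phosphatase that degrades a PI3K product, fell from 19.5 ± 1.79 to 9.26 ± 1.06 CPM (-1.08 ± 0.12, adjusted p = 2.66e-06). IRS1, an insulin receptor adaptor, fell by -0.42 ± 0.080, PIK3CB and RPS6KB2 by -0.33 and -0.30, and IGF1R, PIK3R3 and IRS2 by -0.36, -0.29 and -0.24. The calls of GAB1, DEPTOR, IGF1R, PIK3R3 and IRS2 ended when single libraries were left out: GAB1 without control replicate 3, knockdown replicate 2 or knockdown replicate 3 (adjusted p = 0.106, 0.0832 and 0.098), IGF1R without knockdown replicate 1 or 2 (0.0629 and 0.0643), and DEPTOR without control replicate 3 or any 1 knockdown library (0.0543 to 0.145). PIK3R3 lost its call without control replicate 2 or 3 or knockdown replicate 1 or 3 (0.0707 to 0.13), and IRS2 without any 1 library except control replicate 2 (0.0553 to 0.16). DESeq2 called neither PIK3R3 nor DEPTOR (adjusted p = 0.082 and 0.0843), and edgeR with library size scaling called neither PIK3R3 nor IRS2 (adjusted p = 0.0583 and 0.0818). PIK3CA had a log2 fold change of 0.16 ± 0.073 (adjusted p = 0.122) with 37.09% of its 50-mers shared with KCNMB3, and MTOR one of -0.015 ± 0.061 (adjusted p = 0.894). The test of the list against the other genes did not pass the threshold (camera adjusted p = 0.848, in the lower direction). The median log2 fold change was -0.050 and the mean 0.0024, so the median and the mean differ in sign. Fry gave an adjusted p of 0.696 for movement in 1 direction on balance and an adjusted p of 4.41e-06 for changes in either direction. That second value does not mark out this list: by fry, G2 and mitosis, glycolysis and autophagy had the same 4.41e-06. The other condensin subunits, with 0 called members, had a fry adjusted p of 0.0154 for changes in either direction. The 3' UTRs of AKT1, INSR and IRS1 hold the 7-mer GTGTCAC. RNA levels of these genes do not measure the phosphorylation by which the pathway signals.

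**Figure D2:**
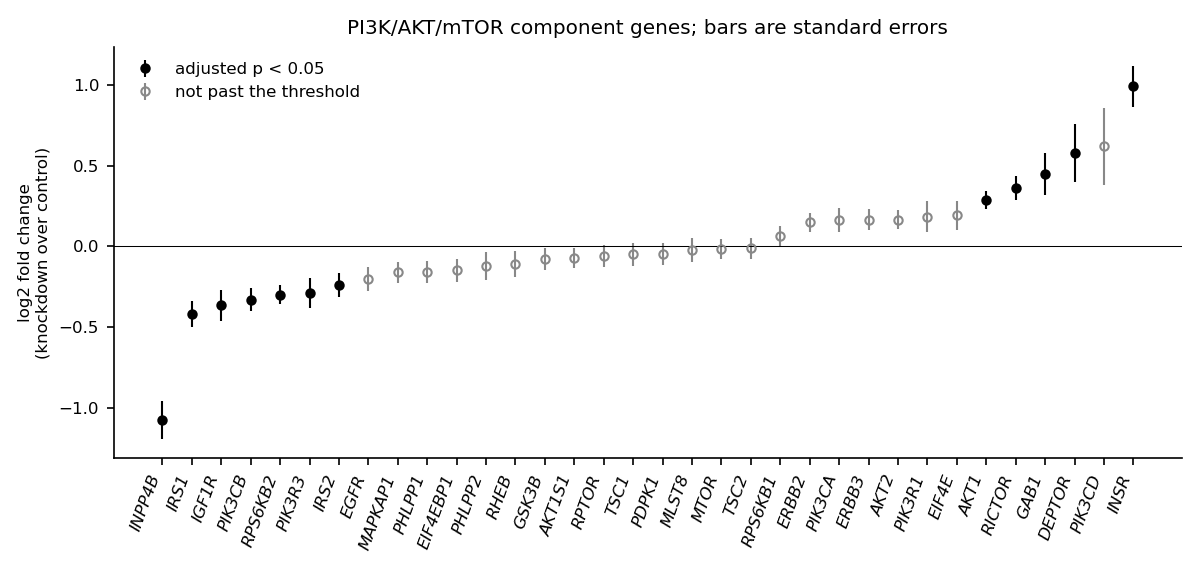
Log2 fold change (knockdown over control, vertical axis) of the 34 tested PI3K/AKT/mTOR component genes, sorted by value, with bars of 1 standard error. Filled points pass the adjusted p threshold of 0.05 (5 higher, 7 lower), from INPP4B at -1.08 to INSR at 0.99.

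Proliferation was examined through cell cycle lists. MKI67, a marker of cycling cells, stood at 912 ± 95.6 CPM in control and 884 ± 69.0 CPM in knockdown cells (log2 fold change -0.044 ± 0.073, adjusted p = 0.715). Of 40 genes of G2 and mitosis, 4 rose, 8 fell and 28 did not pass the threshold (adjusted over the list alone, 4 and 8). The mitotic activator CDC20 fell by -0.43 ± 0.053, the transcription factor FOXM1 by -0.38 ± 0.052 and the chromosomal passenger CDCA8 by -0.44 ± 0.067, while CDC25C and TOP2A rose by 0.48 and 0.26. Exons of FOXM1 overlap those of ITFG2 on the opposite strand. Of 38 genes of G1/S and DNA replication, 5 rose and 9 fell (7 and 9 adjusted over the list alone), with MCM6, a replicative helicase subunit whose 3' UTR holds GTGTCAC, at 0.62 ± 0.057 and its partner MCM2 at -0.24 ± 0.052. ORC1 fell by -0.30 ± 0.067, and CCNE1 (cyclin E1) rose by 0.39. Neither list passed the test against the other genes (camera adjusted p = 0.473 and 0.578).

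Of 13 cohesin genes, STAG2 rose by 0.32 ± 0.055 and CDCA5 (sororin) fell by -0.24 ± 0.059, and the same pair passed adjusted over the list alone. Among 17 genes of homologous recombination and the Fanconi anaemia pathway, RAD51AP1 rose by 0.39 ± 0.074, FANCI rose by 0.17 ± 0.051 and FANCD2 fell by -0.16 ± 0.055, with 2 higher and none lower adjusted over the list alone. Of 21 p53 target genes, GDF15, a stress-induced cytokine, rose by 1.03 ± 0.11 and BBC3 (PUMA) by 0.50 ± 0.17, and PLK3 fell by -0.41 ± 0.11, with 1 higher and 1 lower adjusted over the list alone. CDKN1A and MDM2 of this list had values of -0.03 and 0.03. Of 22 apoptosis regulators, 2 rose and 5 fell, the same numbers as adjusted over the list alone. PMAIP1 (NOXA) fell by -0.44 ± 0.077. None of these lists passed the test against the other genes (camera adjusted p = 0.865, 0.578, 0.848 and 0.635). The median and mean of the apoptosis list differ in sign, at -0.050 and 0.015, with the test in the lower direction. The calls of CDCA5, FANCI, FANCD2, PLK3 and BBC3 each ended when at least 1 of the libraries was left out. Without knockdown replicate 3 all of these calls ended, with adjusted p = 0.0567 for CDCA5, 0.0814 for FANCI, 0.0779 for FANCD2, 0.0771 for PLK3 and 0.0794 for BBC3. FANCD2 was also lost without any 1 of the other libraries (0.0644 to 0.154), BBC3 without control replicate 2 and knockdown replicates 1 and 2 (0.184, 0.116 and 0.11), FANCI without control replicate 3 and knockdown replicate 2 (0.0595 and 0.0902) and PLK3 without control replicate 3 (0.0538). DESeq2 called neither FANCD2 nor BBC3 (adjusted p = 0.0706 and 0.117), and FANCD2 was not called with library size scaling or without the count filter (0.132 and 0.0523).

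Migration was examined through lists of mesenchymal, epithelial and invasion genes. The mesenchymal list passed in the lower direction by camera with its preset correlation: of 17 members tested, 8 fell and 2 rose, also adjusted over the list alone (median log2 fold change -0.33, camera adjusted p = 0.00026). With an estimated correlation the adjusted p was 0.18. FN1 (fibronectin) fell from 196 ± 20.5 to 116 ± 3.38 CPM (-0.76 ± 0.068), COL4A1 (type IV collagen) fell by -0.59 ± 0.063 and SNAI2, a repressor of epithelial genes, fell from 4.63 ± 0.36 to 1.09 ± 0.15 CPM (-2.08 ± 0.24). LOXL2, TGFBI and CTGF fell by -1.23, -1.03 and -0.70, whereas COL6A1 rose by 0.55. VIM (vimentin) was low in both groups, at 2.49 ± 0.60 and 1.79 ± 0.26 CPM (-0.46 ± 0.27, adjusted p = 0.252), and its 3' UTR holds GTGTCAC.

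Epithelial genes moved in both directions, and their list passed in the lower direction by camera with its preset correlation but not with an estimated one. Of 23 epithelial junction and keratin genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 0.00788 (adjusted p = 0.18 with an estimated correlation). KRT18 fell from 1333 ± 139 to 812 ± 69.6 CPM (-0.71 ± 0.075), and KRT7, KRT8 and KRT19 fell by -0.52, -0.47 and -0.43. Annotated exons of KRT18 and KRT8 overlap on opposite strands. The membrane protease ST14 fell by -0.54 ± 0.053. RAB25 (3.11 ± 0.17) and the tight junction protein TJP3 (0.55) rose. CDH1 (E-cadherin) stood at 404 ± 10.9 and 392 ± 20.3 CPM (-0.042 ± 0.055, adjusted p = 0.64).

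The invasion, integrin and matrix protease list was divided, with 9 of 20 members lower and 6 higher (10 and 6 adjusted over the list alone). CD44, a hyaluronan receptor, fell 2.37-fold from 342 ± 13.1 to 144 ± 7.06 CPM (adjusted p = 5.53e-11). PLAU and PLAUR, the protease urokinase and its receptor, fell by -0.62 and -0.51. ITGB6 and MMP7 (matrilysin) rose by 0.77 ± 0.056 and 0.67 ± 0.061, and TNC and ITGAV by 0.56 and 0.34. The list's camera adjusted p was 0.0257 in the lower direction, and 0.695 with an estimated correlation. It was 0.166 without control replicate 1, 0.0878 without knockdown replicate 1 and 0.0551 without knockdown replicate 2.

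The lists of ribosome assembly, amino acid supply and sterol synthesis passed in the lower direction by camera with its preset correlation but not with an estimated one. Of 19 genes of ribosome biogenesis and MYC targets, 12 fell and none rose (13 and 0 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 0.000257 (adjusted p = 0.377 with an estimated correlation). SRM (spermidine synthase) fell by -0.53 ± 0.073, and the ribosome assembly factors BOP1 and RRP12 fell by -0.40 ± 0.055 and -0.33 ± 0.063. Of 19 genes of the ATF4 and amino acid response, 6 fell and 1 rose (7 and 1 adjusted over the list alone), with a camera adjusted p of 0.00248 (adjusted p = 0.18 with an estimated correlation). SLC7A5 and SLC3A2, the chains of a large neutral amino acid transporter, fell from 499 ± 19.2 to 245 ± 6.12 CPM (-1.03 ± 0.054) and by -0.53 ± 0.055, and the serine synthesis enzyme PSAT1 fell by -0.46 ± 0.061. ATF4 itself had a value of 0.10. Of 28 cholesterol and fatty acid synthesis genes, 9 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.18 with an estimated correlation). DHCR7 and MVD, enzymes of cholesterol synthesis, fell by -0.37 ± 0.053 and -0.38 ± 0.057, and FASN (fatty acid synthase) fell by -0.34.

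The lists of hypoxia response, glycolysis and FOXO target genes passed in the higher direction by camera with its preset correlation but not with an estimated one. Of 16 hypoxia genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.00835 (adjusted p = 0.18 with an estimated correlation). The mitophagy receptors BNIP3 and BNIP3L rose by 0.67 ± 0.062 and 0.49 ± 0.057, and VEGFA by 0.24, while NDRG1 fell by -0.64 ± 0.054. Of 20 glycolysis genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with ENO2 at 0.73 ± 0.065 and PFKFB3 at 0.43 ± 0.054, and the glucose transporter SLC2A1 fell from 901 ± 31.2 to 646 ± 10.1 CPM (-0.48 ± 0.054). The 3' UTR of ENO2 holds GTGTCAC. Of 17 FOXO target genes, 5 rose and 2 fell (7 and 2 adjusted over the list alone), among them CCNG2 (cyclin G2) at 0.83 ± 0.081, INSR at 0.99 ± 0.13 and TRIB1 at 0.45 ± 0.081. The camera adjusted p was 0.0313 for glycolysis and 0.0338 for FOXO targets, with an adjusted p of 0.559 and 0.534 with an estimated correlation. For glycolysis it was 0.114 without control replicate 1 and 0.0714 without knockdown replicate 1, and for FOXO targets 0.138 without control replicate 2 and 0.0678 without knockdown replicate 2.

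**Figure D3:**
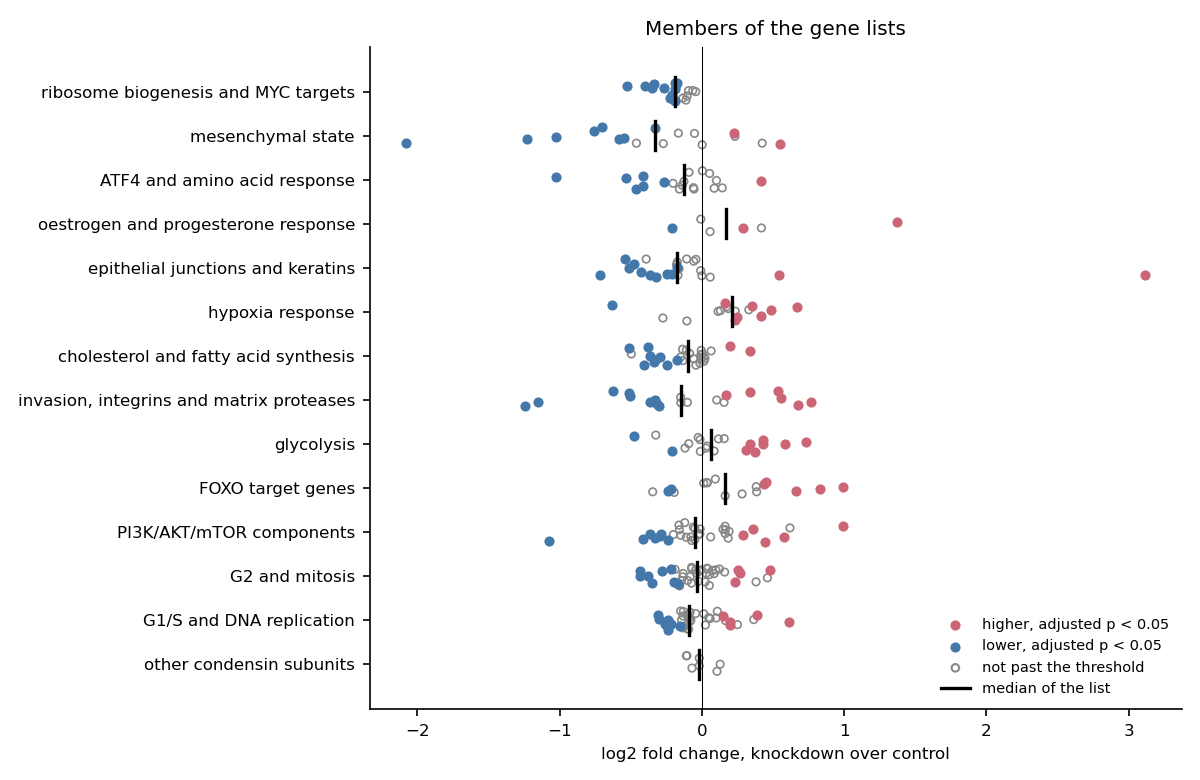
Log2 fold change (knockdown over control, horizontal axis) of each tested member of 14 gene lists, 1 list per row, with the list's median as a black line and red or blue points for members past the adjusted p threshold of 0.05. The upper 10 rows are the lists with a camera adjusted p under 0.05 at the preset correlation, where ribosome biogenesis (median -0.19) and the mesenchymal list (median -0.33) lie to the left and the hypoxia list (median 0.21) to the right of 0. With an estimated correlation none of these 10 lists passed (camera adjusted p from 0.18 to 0.695).

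Of 22 autophagy and lysosome genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone), with ULK1 at 0.54 ± 0.071, TFEB at 0.44 ± 0.11 and TFE3 at -0.29 ± 0.061 (camera adjusted p = 0.925, with a median of -0.0067, a mean of 0.033 and the test in the higher direction). Of 14 endoplasmic reticulum chaperone and unfolded protein response genes, DNAJC3 fell by -0.27 ± 0.072 and the others did not pass the threshold, also adjusted over the list alone (camera adjusted p = 0.635). The call of DNAJC3 ended without knockdown replicate 1 (adjusted p = 0.0525). Of 28 nuclear genes of oxidative phosphorylation, 0 passed the threshold in the edgeR test, also adjusted over the list alone, against 4 at an unadjusted p below 0.05 and 0 by DESeq2 and by limma-voom (camera adjusted p = 0.848), and ATP5F1B had a value of -0.15 ± 0.060. The 3' UTR of ULK1 holds GTGTCAC.

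Signalling and cytokine lists held members that moved in both directions. Of 18 MAPK feedback and target genes, 5 fell and 2 rose, also adjusted over the list alone, with FOSL1, an AP-1 subunit, at -0.59 ± 0.078, HBEGF at -0.90, DUSP5 at 0.43 ± 0.064 and ETV1 at 0.43 ± 0.080 (camera adjusted p = 0.635). Of 10 immediate-early genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone), with DUSP1 and KLF4 at -0.55 ± 0.093 and -0.55 ± 0.11 and JUNB at 0.37 ± 0.067 (camera adjusted p = 0.938, with a median of -0.014, a mean of 0.071 and the test in the lower direction). Of 14 NF-kB and cytokine genes, the chemokine CCL20 rose 2.38-fold from 3.04 ± 1.01 to 7.22 ± 1.35 CPM, CXCL3 rose by 0.94, SOD2 rose by 0.41 ± 0.061 and IL32 fell by -1.16 ± 0.12 (3 and 1 also adjusted over the list alone, camera adjusted p = 0.865, with a median of -0.030, a mean of 0.092 and the test in the higher direction). The 3' UTR of SOD2 holds GTGTCAC, and its call ended with the GC and length trend removed (adjusted p = 0.0508), where its log2 fold change was 0.34 ± 0.107, a smaller change with a larger SE. Of 22 interferon response genes, 4 rose and 2 fell, also adjusted over the list alone, with IFIT1 and IFIT2 at 0.41 ± 0.073 and 0.38 ± 0.068 (camera adjusted p = 0.336). The oestrogen and progesterone response list had 6 tested members and a camera adjusted p of 0.00505 (adjusted p = 0.18 with an estimated correlation). Its 2 higher and 1 lower members, also adjusted over the list alone, were CA12 (carbonic anhydrase 12), up from 52.8 ± 3.37 to 137 ± 5.96 CPM, PDZK1 at 0.29 ± 0.075 and CTSD at -0.21 ± 0.072. Of the 50-mers of PDZK1, 65.93% occur in other genes, and 60.56% of those of CTSD, whose call ended without control replicate 3, knockdown replicate 2 or knockdown replicate 3 (adjusted p = 0.183, 0.112 and 0.251) and with DESeq2 or library size scaling (adjusted p = 0.064 and 0.0898), so both are uncertain.

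Few markers of other cell types were abundant enough to test. Of 10 fibroblast markers, COL1A1 was the 1 tested and rose from 15.6 ± 0.79 CPM by 0.44 ± 0.095, also adjusted over the list alone (camera adjusted p = 0.273), and its 3' UTR holds GTGTCAC. Of 3 immune and 3 endothelial markers tested, 0 and 0 passed the threshold in the edgeR test, also adjusted over each list alone, with 0 and 1 at an unadjusted p below 0.05 and 0 in both lists by DESeq2 and by limma-voom (camera adjusted p = 0.868 and 0.985), with CD68 at 1.68 ± 0.062 and PECAM1 at 1.12 ± 0.42 CPM in control cells. Reads of CD68, MT-CO1 and RPSA are shared with other genes, at 97.43%, 49.5% and 27.38% of their 50-mers. Mitochondrially encoded genes took 5.016% to 5.679% of the counts in control and 5.27% to 5.613% in knockdown libraries, and 0 of 13 passed the threshold in the edgeR test, also adjusted over the list alone, against 1 at an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom (camera adjusted p = 0.848), with MT-CO1 at 0.075 ± 0.072. Of 54 cytosolic ribosomal protein genes, 2 rose and 1 fell, with RPS16 at 0.21 ± 0.069 and RPSA at -0.31 ± 0.069 (0 and 1 adjusted over the list alone, camera adjusted p = 0.985). The call of RPS16 ended without control replicate 1 (adjusted p = 0.0836), knockdown replicate 1 (0.187) or knockdown replicate 2 (0.077), and without control replicate 1 the list's camera adjusted p was 0.0131, in the lower direction. Of 8 replication-dependent histone genes, HIST1H1C rose by 0.67 ± 0.12, also adjusted over the list alone (camera adjusted p = 0.68).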

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

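Removal of GC and length trends and removal of the 20 most abundant genes were chosen after the data had been seen. NCAPG kept its direction and call under each alternative that gave it a value, with log2 fold changes from -1.38 to -1.28. The counts of 1318 higher and 1438 lower genes stayed within 1.5 times under DESeq2 (1018 and 1155), limma-voom, RLE scaling, library size scaling (1689 and 1050, where the median of all genes moved by 0.039), both count filters and both added settings. At an adjusted p below 0.01 they were 743 and 821, because the threshold is stricter. Leaving out 1 library gave 880 to 1541 higher and 867 to 1508 lower genes, with fewer libraries to test. The replicate numbers share no day or batch in the labels. With the number as a replicate block, 1042 genes were higher and 1080 lower, 2112 genes kept their call and direction, and 6 calls of genes under the naming rule ended (among them FANCI, FANCD2, BBC3, CTSD and RPS16), as did that of IRS2 (0.0589), but no list call. Named calls also ended under DESeq2 (3), library size scaling (2), no filter (1) and GC and length removal (1). Same-numbered libraries did not each correlate best with their own number (-0.107, 0.029 and -0.0263). The list of PI3K/AKT/mTOR components did not pass the threshold in any setting, with p between 0.314 and 0.886 over the leave-one-out fits. Its direction reversed without control replicate 1, where p was 0.886. Estimating the correlation ended the calls of 10 other lists, the only lists that had a call to lose. The estimate was below the preset 0.01 for the mesenchymal (-0.0411), epithelial (-0.0402), oestrogen (-0.11), cholesterol (-0.00836) and ATF4 (-0.00112) lists. A correlation above the preset therefore does not account for the loss of those calls. The estimate was 0.0107 for hypoxia, 0.0755 for FOXO targets, 0.127 for glycolysis, 0.196 for ribosome biogenesis and 0.229 for invasion. Leaving out a library ended calls in 7 list fits, of the glycolysis, FOXO target and invasion lists, and in 29 named-gene fits. The 180 list fits and 576 named-gene fits run also include lists and genes not called with all 6 libraries, so they are no base for a rate of loss. The cause of the lost calls was not tested. Fry, which does not set a list against the other genes, was also run for movement in 1 direction. For the 10 lists called by camera its adjusted p ran from 0.00108 (epithelial) to 0.0274 (glycolysis), except for invasion (0.064). It was also below 0.05 for 3 lists that camera did not call: p53 targets and interferon (0.0152 each) and fibroblast markers (0.00249, 1 gene tested). The signs that turned belonged to values not called with all 6 libraries. MTOR (-0.069 to 0.051 over the leave-one-out fits) was 0.023 with library size scaling, 0.051 without control replicate 1, 0.0090 without knockdown replicate 1 and 0.0044 with the GC trend removed. MKI67 (-0.11 to 0.048) was 0.048 without control replicate 1 and 0.018 without knockdown replicate 1, and CDH1 (-0.070 to 0.00050) was 0.00050 without the latter. List directions turned, at the adjusted p given, for condensin (leave-one-out range 0.805 to 0.97, 0.968 with library size scaling, 0.937 without control replicate 1), ribosomal proteins (0.0131 to 0.838, 0.963 with library size scaling, 0.185 without control replicate 2, 0.687 without control replicate 3, 0.379 without knockdown replicate 3), oxidative phosphorylation (0.145 to 0.962, 0.446 without control replicate 1, 0.962 without knockdown replicate 1), endothelial markers (0.645 to 0.97, 0.906 without control replicate 1, 0.954 with the GC trend removed), mitochondrial genes (0.377 to 0.918, 0.796 without control replicate 2, 0.918 without knockdown replicate 3), immune markers (0.681 to 0.962, 0.962 without knockdown replicate 1), immediate-early genes (0.806 to 0.97, 0.918 without knockdown replicate 3, 0.849 with the GC trend removed) and cohesin (0.932 with the GC trend removed). In the simulated data 57.1% of the smallest changes were recovered. That simulation gave 178 calls against 2756 in the real comparison, so it demanded a smaller unadjusted p for a call. Its share therefore does not carry over to the real comparison.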

Other observations

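The tests of 4 further gene lists were chosen after the fold changes had been seen, those of the 7-mer GTGTCAC after it had come out of the search, and that of abundant genes after removing them had moved almost no calls, while the others in this part were set before their results. Many actin cytoskeleton genes and YAP/TAZ target genes, which the report does not cover as groups, were lower in knockdown cells. With an estimated correlation, movement of either group beyond the genes that drew attention to it was not shown after adjustment. Of 24 YAP/TAZ targets tested, 17 fell and 0 rose at an adjusted p below 0.05 in the edgeR test (1 higher at an unadjusted p below 0.05, and 0 by DESeq2 and by limma-voom), among them NT5E (-1.10 ± 0.055), ANKRD1 (-1.83 ± 0.19), CTGF (-0.70), FJX1 (-0.55) and CYR61 (-0.33). Of 30 actin cytoskeleton and SRF target genes, 14 fell and 1, SRF itself (0.24), rose. FHL2 fell by -1.05, TPM1 by -0.66, CNN3 by -1.40 and ACTG1 by -0.28. The call of SRF ended without control replicate 3 or knockdown replicate 2. Other calls in these counts were also lost in some of the alternative fits. Among YAP/TAZ targets, those of AMOTL2, IGFBP3 and LATS2 held in 8, 7 and 5 of 15 fits, and DESeq2 called 15 targets lower. In the actin list, that of LIMA1 held in 5 of 15 fits and that of FLNA in 5 of 14. Over all members, including those that drew attention, the adjusted p with an estimated correlation was 0.0342 for both lists, so this value is no independent test. Several genes of kidney proximal tubule also rose from control means under 1 CPM, including ACSM2A (3.24), ACSM2B (3.19), SLC17A3 (2.69) and DPEP1 (1.77). The aldo-keto reductases AKR1C1 (1.56), AKR1C2 (1.45) and AKR1C3 (1.38) rose from higher control means of 6.07, 4.63 and 26.2 CPM. Counts of the AKR1C genes are uncertain as close paralogs, like those of ACSM2A and ACSM2B.

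Whether these groups moved beyond the genes that drew attention to them was tested on the members not seen before, by camera with an estimated correlation. Lower YAP/TAZ target expression as a group may be present: 13 of 20 unseen targets fell and 0 rose, with a mean log2 fold change of -0.256, but p was 0.101, so the set remains open. For the actin and SRF list, 10 of 25 unseen members fell and 1 rose (mean -0.165), and p was 0.0325, or 0.13 after adjustment over the 4 lists, which fails the correction. For the proximal tubule list, 3 of 11 unseen members rose and 0 fell, the mean was -0.000945 and p was 0.467. For NRF2 targets, 1 of 20 unseen members rose (AKR1C2) and 7 fell, the mean was -0.000606 and p was 0.447. Camera with its preset correlation gave the unseen members an unadjusted p of 6.43e-06 for YAP/TAZ targets and 0.000489 for the actin list. For the proximal tubule and NRF2 lists it gave 0.128 and 0.229. The result for the YAP/TAZ and actin lists therefore depends on how the correlation is set.

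The first pattern weighed is the number of called genes, for which the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, the 1 split with as many calls, gave 2756 genes and the highest of the others 0 by edgeR, with at most 859 genes at an unadjusted p below 0.05 against 4267. Bias from GC content or transcript length is argued against, since 97.46% of the called genes were still called in the same direction once those trends were removed. Distortion by a few abundant genes is argued against, since the 20 most abundant genes of each library held 8.763% to 9.46% of its counts, a range that can shift other genes by at most 0.0111 in log2 terms, below the change less 2 SE of every called gene (smallest 0.0422). Knockdown of NCAPG, the biology named by the design, is confounded with the difference between constructs, since all 3 knockdown libraries differ from all 3 controls in both.

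The second pattern is the set of 1438 lower genes, which could hold transcripts silenced off target by the NCAPG construct. Such silencing works through a short seed match in 3' UTRs, so a 7-mer shared by lower genes was searched for among 15990 7-mers in 12285 genes, adjusting for 3' UTR length and GC content. The most negative 7-mer had t = -4.056 (Bonferroni adjusted p = 0.798), and among the 3807 7-mers that occur in NCAPG transcripts the most negative had a t of -3.893 (adjusted p = 0.377). In simulated data a shift of -0.15 in the carriers of 1 7-mer ranked that 7-mer first in 5 of 5 runs, so a seed effect as the main source of the lower genes is argued against, and a smaller or rarer one stays open. Reads shared with paralogs are argued against as the source of the named lower genes as a set, whose 50-mers occur in other genes at a median of 0.04%, but stay open for the 7 of 47 above 20% (NCAPG, KRT81, FOXM1, MCM2, KRT18, CTSD and RPSA).

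The third pattern came from the same search, which gave 1 7-mer past the threshold in higher genes, GTGTCAC (t = 5.491, Bonferroni adjusted p = 0.000638): of 1281 genes with it 16.55% were called higher and 7.338% lower, against 10.01% and 12.18% of the 11004 without it. A candidate explanation is silencing of such genes in the control cells (AKT1 and INSR carry the 7-mer and rose, while CDK6 at -1.93 and IRS1 at -0.42 carry it and fell). For a guide with GTGTCAC opposite the usual seed at positions 2 to 8, it predicts a larger shift for the extended site GTGTCACA. The 402 genes with that site lay 0.0583 ± 0.023 (SE) above the other carriers (permutation p = 0.00582 over genes). This difference was at most 0.0358 in size in the other 9 splits of the libraries. Those splits set unequal mixes of both groups against each other, so part of the real difference remained in them. They give no chance level for it and are too few to settle it. The control construct's sequence was not given in the sources used here and the design text calls it an empty vector, which would hold no guide, while a non-targeting sequence in common use, TTCTCCGAACGTGTCACGT, noticed after the search, contains GTGTCAC opposite guide positions 3 to 9 and, for the usual seed at positions 2 to 8, a 7-mer with a t of 1.608. In that sequence GTGTCAC is followed by G, not by A, and is not opposite positions 2 to 8. The prediction for the extended site therefore does not apply to that sequence. A trend with GC content or length is argued against (t = 5.562 with it removed). Chance stays open, since both permutations over genes, that of the extended site and the one that set the bound (0 of 200 gave a t as large), were wrong in ignoring variation that genes share within a library, and another split of the libraries reached 5.449 with a different 7-mer. GTGTCAC ranked first in every leave-one-out fit (t from 5.107 to 5.463), but these fits share most of their libraries and so do not test chance.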
